A study of Mus musculus with 6 samples.

How the data were processed

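RNA sequencing of mouse pylorus was available for 6 libraries, 3 labelled Sox2 WT and 3 labelled Sox2 KO. Per the labels' protocols, Sox2 KO mice carried CreER at Rosa26 and floxed Sox2 alleles, Sox2 WT mice carried the floxed alleles without CreER, and both received tamoxifen at 8 weeks of age, with collection 2 weeks later. The age label of each sample says 8 weeks, while the series text gives an age of 10 weeks at collection. The mice were of a mixed strain background. The muscle layer was separated after cold incubation, and total RNA came from the remaining epithelium and mesenchyme. The labels number 3 samples in each group and speak of mice, but do not say that each library is a separate animal, so the p-values measure the spread between these libraries.

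The values are RPKM, computed by the authors and deposited for 39179 Ensembl genes. Per the submitters' processing notes, CASAVA 1.7 and STAR were used with the mouse build mm10. The counting tool, the annotation, the filters and the strandedness of the libraries are not given in the sources used here. The 6 deposited columns of the series table equal the 6 single-library tables. Gene coordinates were taken from GENCODE mouse release 21 on the build GRCm38, which is mm10, for the 37693 identifiers that matched. Without strand information, reads of overlapping genes and of near-identical copies cannot be told apart.

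Whole reads were recovered from the deposited RPKM with 1 length per gene and 1 denominator per library. The values of 100% of the 23538 genes above 0 came out whole within a tolerance of 1e-05 reads. Each length was searched for to make the values whole, so this share is a weak check for genes above 0 in few libraries. The recovered reads in genes numbered 26549019, 32941667 and 31525851 in Sox2 WT replicates 1 to 3, and 38726280, 35590123 and 38988625 in Sox2 KO replicates 1 to 3. The denominators behind the RPKM were lower than these sums, so that the sum was 110% to 130% of the denominator. For some genes, among them Zg16, Tph1, Prom1, Cdkn1a, Mcm6, Ptprc and Cela1, the recovered reads were even in every library. The length used for such genes may be a multiple of the true one, which would make their reads and the sums too high. The sums therefore do not decide whether the RPKM were scaled to the reads counted in genes. At 3 reads or fewer, counting error alone is large, so genes with low values were filtered.

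Values were tested as log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and moderated variances, over genes with a mean RPKM of at least 0.5 across the 6 libraries. Of rows that shared a symbol, the row with the highest mean was kept. This left 14045 genes. Fold changes are Sox2 KO minus Sox2 WT on the log2(RPKM + 0.5) scale, which understates the change of genes with low values, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The level of Sox2 was also compared with an exact two-sided permutation test. Before the data were examined, 26 gene lists of cell types, pathways and sex-linked genes were fixed. The 24 lists with at least 3 tested members, the sex-linked list aside, were tested as a family with limma's camera at a preset inter-gene correlation of 0.01 with the same variance trend, and again with an estimated correlation and with fry. Counts of list members are given over all genes tested and adjusted over the list alone. Genes within 10 Mb of the Rosa26 locus were compared with all other tested genes by Fisher's exact test.

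The rule for named genes was also fixed before the data were examined. It takes Sox2; the 12 largest changes in each direction among genes past the threshold whose 3 Sox2 KO values do not overlap the 3 Sox2 WT values and whose mean RPKM is at least 1; where fewer than 5 genes pass in a direction, the 6 such genes with the smallest unadjusted p; and, from each list, up to 4 passing members or, where none passes, the 2 with the highest mean RPKM. Predicted genes, immunoglobulin and T-cell receptor segments and sex-linked genes are left out of the first part. The 55 further genes, among them most named members of the tuft, enteroendocrine, interferon and haemoglobin lists, were chosen after their values were seen. Some genes that these choices take in are not reported here.

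The alternatives fixed beforehand were a pseudocount of 0.1 or 1, no filter or a mean RPKM of at least 1, rescaling by median-of-ratios factors, quantile normalization, a robust variance estimate, no variance trend, the replicate number as a block, all rows kept, sample quality weights, each library left out in turn, an adjusted p under 0.1, an added fold change of at least 2, and windows of 5 and 20 Mb. After the data were seen, 5 were added: the sex of the animal as a covariate, read from Xist and Y-linked genes, male libraries alone, genes on X and Y left out, protein-coding genes alone, and limma's voom on the recovered reads. In the male libraries, the lone Sox2 WT library was assumed to vary like the others. The median log2 fold change of all genes was 0.02, and rescaling moved it by less than 0.1.

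The tests were tried on simulated data made for this comparison with 14045 genes and 200 changed genes in each of 5 draws. Of genes changed by 1 on the log2 scale, 69.0% were recovered, and of genes changed by 2, 95.2%; 50 of 871 calls were false. In 20 draws, camera called 20 of 20 lists of 10 genes raised by 0.5, and 2 of 500 unchanged lists. The simulated genes vary independently within a list, which real genes do not. The simulation also holds no differences of sex or tissue make-up between libraries. With 200 changed genes in a draw, the adjustment is milder than with the 4 genes called in the real data. The shares recovered therefore need not hold for the real libraries, where Itln1, at a log2 fold change of 4.93, did not pass. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.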

Results

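The libraries measured gene expression in the pylorus, the part of the stomach next to the duodenum, in 2 groups of 3. In Sox2 KO mice a tamoxifen-activated Cre recombinase expressed from the Rosa26 locus could delete floxed Sox2, which encodes a SOX-family transcription factor of stem and progenitor cells; Sox2 WT mice had the same floxed gene and no Cre. Between 20180 and 20550 genes had a value above 0 in each library. The reads recovered in genes, sums that may be too high, ranged from 26549019 in Sox2 WT replicate 1 to 38988625 in Sox2 KO replicate 3. Xist, transcribed from the inactive X chromosome, was at 36.3 and 33.3 RPKM in Sox2 WT replicates 2 and 3 and at most 0.0124 RPKM in the other libraries, while the Y-linked gene Ddx3y was between 10.3 and 13.1 RPKM in Sox2 WT replicate 1 and the 3 Sox2 KO libraries and listed at 0 in the other 2. By these genes, 2 of the 3 Sox2 WT libraries were female and the 3 Sox2 KO libraries were male, so that sex differed along with genotype. A fold change with sex as a covariate is therefore Sox2 KO minus Sox2 WT replicate 1, the 1 male Sox2 WT library.

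Sox2, the targeted gene (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461, mm10), was far lower in each Sox2 KO library. Its level was 11.1, 9.03 and 10.9 RPKM in Sox2 WT replicates 1 to 3, from 657, 622 and 683 reads, and 25, 15 and 35 reads remained in Sox2 KO replicates 1 to 3. The Sox2 KO mean of 0.324 ± 0.106 RPKM (SD, n = 3) was 3.13% of the Sox2 WT mean of 10.3 ± 1.13 RPKM (SD, n = 3). The log2 fold change was -3.72 (SE 0.147, limma adjusted p = 2.9e-04). An exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest value that design allows. Leaving out any 1 library kept the call. With the sex of the animals as a covariate the log2 fold change of Sox2 was -3.82 (limma adjusted p = 0.0277), and in the male libraries alone, with 1 Sox2 WT library, it was -3.82 and did not pass (adjusted p = 0.154). The range over all alternatives was 9.0e-06 to 0.154.

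**Figure D1:**
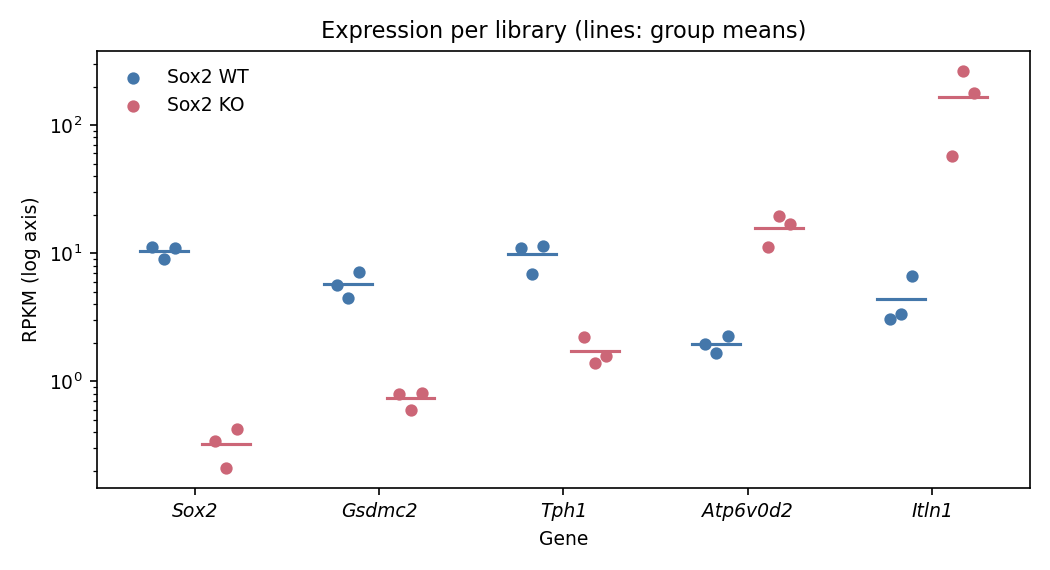
RPKM on a log axis of 5 genes in the 3 Sox2 WT (blue) and 3 Sox2 KO (red) libraries, with 1 point per library and a line at each group mean. Sox2 fell from a mean of 10.3 to 0.324 RPKM, and for each gene shown the 2 groups do not overlap; Tph1 and Itln1 did not pass the threshold over all genes.

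The comparison of Sox2 KO with Sox2 WT asks which other genes of the pylorus differ once Sox2 is deleted. Few passed the test. Atp6v0d2, a subunit of the vacuolar proton pump, rose from 1.94 ± 0.298 to 15.8 ± 4.27 RPKM (SD, n = 3 each; log2 fold change 2.71, SE 0.210, limma adjusted p = 0.0123). Gsdmc2, a gasdermin gene with close paralogs on chromosome 15, fell from 5.71 ± 1.31 to 0.734 ± 0.122 RPKM (SD, n = 3 each; log2 fold change -2.31, SE 0.178, limma adjusted p = 0.0123).

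Of 14045 genes, limma put 4 past the threshold, 2 higher and 2 lower in Sox2 KO. An unadjusted p under 0.05 was reached by 442 genes, against 702 that chance would give, and the 3 Sox2 KO values did not overlap the 3 Sox2 WT values in 995 genes (7.08%, against 10% by chance). Under median-of-ratios rescaling and under quantile normalization 1 gene was higher and 2 were lower. Leaving out 1 library ended the calls of Atp6v0d2 and Gsdmc2 as follows. Atp6v0d2 had a limma adjusted p of 0.0612, 0.0576 and 0.0504 without Sox2 WT replicates 1, 2 and 3, and 0.0573 and 0.0761 without Sox2 KO replicates 2 and 3. Gsdmc2 had 0.0612 and 0.0504 without Sox2 WT replicates 1 and 3, and 0.0729 and 0.0752 without Sox2 KO replicates 2 and 3. With sex as a covariate both had an adjusted p of 0.389, at log2 fold changes of 2.70 for Atp6v0d2 and -2.31 for Gsdmc2. Over all alternatives the adjusted p ran from 6.1e-04 to 0.560 for Atp6v0d2 and 3.7e-04 to 0.389 for Gsdmc2. In the male libraries alone limma called 0 genes, and 583 had an unadjusted p under 0.05.

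The genes next in order did not pass. On the lower side, Tph1, which encodes the first enzyme of serotonin synthesis in enterochromaffin cells, was at 9.78 ± 2.52 RPKM in Sox2 WT and 1.72 ± 0.436 RPKM in Sox2 KO (SD, n = 3 each; log2 fold change -2.19, limma adjusted p = 0.0501). The phospholipid synthesis gene Pcyt1b (log2 fold change -1.11, adjusted p = 0.0561), the stanniocalcin gene Stc2 (-1.36, adjusted p = 0.0577) and the synaptic scaffold gene Homer2 (-0.92, adjusted p = 0.111) followed. On the higher side, Itln1, encoding an intelectin secreted by goblet and Paneth cells, was at 4.35 ± 2.02 RPKM in Sox2 WT and 167 ± 105 RPKM in Sox2 KO (SD, n = 3 each; log2 fold change 4.93, adjusted p = 0.0577). Zg16, another secreted lectin of goblet cells, was at 46.3 ± 37.1 and 685 ± 279 RPKM (SD, n = 3 each; log2 fold change 4.06, adjusted p = 0.127). Gng13, a G protein subunit of taste and tuft cells (1.24, adjusted p = 0.111), and Spib, an ETS-family transcription factor (1.31, adjusted p = 0.127), completed the 6 with the smallest p on that side, all from limma. In the annotation Gng13 overlaps Chtf18, and Zg16 and Homer2 each overlap a predicted gene. Without 1 library some of these passed: Tph1 without Sox2 WT replicate 2 (adjusted p = 0.0292) or Sox2 KO replicate 1 (0.0448), Stc2 and Itln1 without Sox2 KO replicate 1 (0.0448 and 0.00513), and Zg16 without Sox2 WT replicate 1 (log2 fold change 4.67, adjusted p = 0.0353). With sex as a covariate, and in the male libraries alone, the log2 fold change of Zg16 was 2.84, with an adjusted p of 0.479 and 0.707. Over all alternatives the adjusted p ran from 9.3e-04 to 0.530 for Tph1, 0.00163 to 0.706 for Stc2, 0.00224 to 0.611 for Itln1 and 0.00572 to 0.707 for Zg16.

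The tuft cell list rose as a set. Tuft cells are chemosensory cells of the gut epithelium. All 8 tested members had a positive log2 fold change, with a median of 0.93, and in 7 of them the 3 Sox2 KO libraries lay above the 3 Sox2 WT libraries, with a median deviation of 0.38, 0.82 and 0.24 in Sox2 KO replicates 1, 2 and 3 (camera adjusted p = 8.9e-18, and adjusted p = 0.286 with an estimated correlation). Over all genes, 0 of the 8 passed; adjusted over the list alone, 7 did. Sh2d6 had a log2 fold change of 1.47 (SE 0.222), the taste-pathway channel gene Trpm5 of 1.07 (SE 0.173) and Pou2f3, the transcription factor that specifies tuft cells, of 0.85 (SE 0.192). Ptgs1 had a log2 fold change of 0.33 (SE 0.0931), and Avil, the 1 member not past the threshold within the list, of 0.20 (SE 0.235). With sex as a covariate, and thus against Sox2 WT replicate 1 alone, the median was 1.06 and the call held (camera adjusted p = 1.3e-10). The range of the adjusted p over all alternatives was 4.8e-19 to 0.286.

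The enteroendocrine list, markers of hormone-secreting cells, had a median log2 fold change of -0.23. It passed downwards (camera adjusted p = 6.6e-07, and adjusted p = 0.302 with an estimated correlation). By library its median deviation was 0.40, 0.14 and -0.16 in Sox2 WT replicates 1 to 3. In Sox2 KO replicates 1 to 3 it was -0.22, -0.12 and -0.06, so the list overlapped between the groups. Of its 18 tested members 13 had a negative and 5 a positive log2 fold change; 0 passed over all genes, and Tph1 and the granin gene Chgb (-0.97, SE 0.176) passed adjusted over the list alone. The values of the main pyloric hormone genes overlapped between the groups: gastrin, Gast, was at 4312 ± 1807 RPKM in Sox2 WT and 4433 ± 1664 RPKM in Sox2 KO (SD, n = 3 each; log2 fold change 0.04, SE 0.421, and -0.27 under quantile normalization), somatostatin, Sst, had a log2 fold change of 0.15 (SE 0.359) and ghrelin, Ghrl, of -0.01 (SE 0.579). Cck, the cholecystokinin gene, was at 1.46 ± 0.403 RPKM in Sox2 WT and 7.56 ± 4.99 RPKM in Sox2 KO (SD, n = 3 each; log2 fold change 1.79, limma adjusted p = 1.00 over all genes, and 0.0448 without Sox2 KO replicate 1). With sex as a covariate the median of the list was -0.52 and its camera adjusted p 1.2e-09, within a range over all alternatives of 1.2e-09 to 0.446. That median sets Sox2 KO against Sox2 WT replicate 1 alone, the library with the highest median deviation, 0.40.

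**Figure D2:**
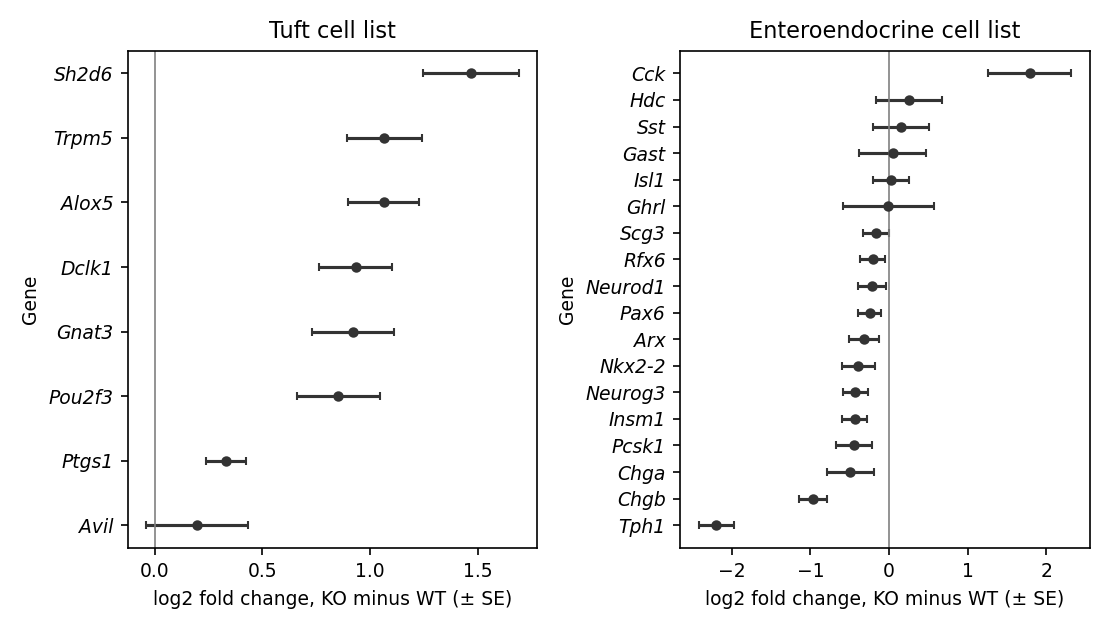
Log2 fold change of each tested member of the tuft cell list (left) and the enteroendocrine list (right), Sox2 KO minus Sox2 WT, with bars of 1 SE and n = 3 libraries per group. The 8 tuft members lie above 0, from 0.20 for Avil to 1.47 for Sh2d6, while 13 of 18 enteroendocrine members lie under 0, with Tph1 at -2.19 and Cck at 1.79.

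The interferon response and haemoglobin lists also rose as sets. With sex as a covariate, again against Sox2 WT replicate 1 alone, both calls ended. The median log2 fold change went from 0.61 to 0.30 for interferon genes and from 0.64 to 0.50 for haemoglobin genes. The 15 tested interferon genes had positive log2 fold changes with a median of 0.61 (camera adjusted p = 1.9e-08, and adjusted p = 0.415 with an estimated correlation; adjusted p = 0.0712 with the sex covariate; range over all alternatives 2.0e-11 to 0.474); 0 passed over all genes or adjusted over the list alone. The median deviation of the list was highest in Sox2 KO replicate 2, at 0.55, and under 0.1 in each other library: Isg15 was at 12.8 RPKM there and at 2.98 and 4.07 RPKM in Sox2 KO replicates 1 and 3, against 4.34, 2.08 and 1.51 RPKM in Sox2 WT replicates 1 to 3. Oas1a, of the antiviral oligoadenylate synthetases, had a log2 fold change of 0.41. The 4 tested haemoglobin genes, a sign of blood in the tissue, had a median log2 fold change of 0.64 (camera adjusted p = 1.6e-05, and adjusted p = 0.302 with an estimated correlation; adjusted p = 0.0692 with the sex covariate; range over all alternatives 2.6e-06 to 0.401). The median deviation of these genes was 0.76 in Sox2 KO replicate 2, and 0.10 and 0.14 in Sox2 KO replicates 1 and 3. Hbb-bs was at 2.65 ± 0.623 RPKM in Sox2 WT and 4.91 ± 1.47 RPKM in Sox2 KO (SD, n = 3 each); 0 of the 4 passed over all genes and 4 adjusted over the list alone, and these genes are near-identical pairs whose reads cannot be told apart.

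The SOX family list contains the deleted gene, whose fall enters its test (camera adjusted p = 0.00687, and adjusted p = 0.302 with an estimated correlation; range over all alternatives 6.8e-04 to 0.364; adjusted p = 0.126 without Sox2 WT replicate 2), with Sox2 the 1 of its 8 tested members that passed. The median of the list was -0.04, and the other 7 members ran from -0.38 for Sox21 (SE 0.247) to 0.15 for Sox17 (SE 0.219), 3 of them positive, with Sox9 at -0.01 (SE 0.113).

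**Figure D3:**
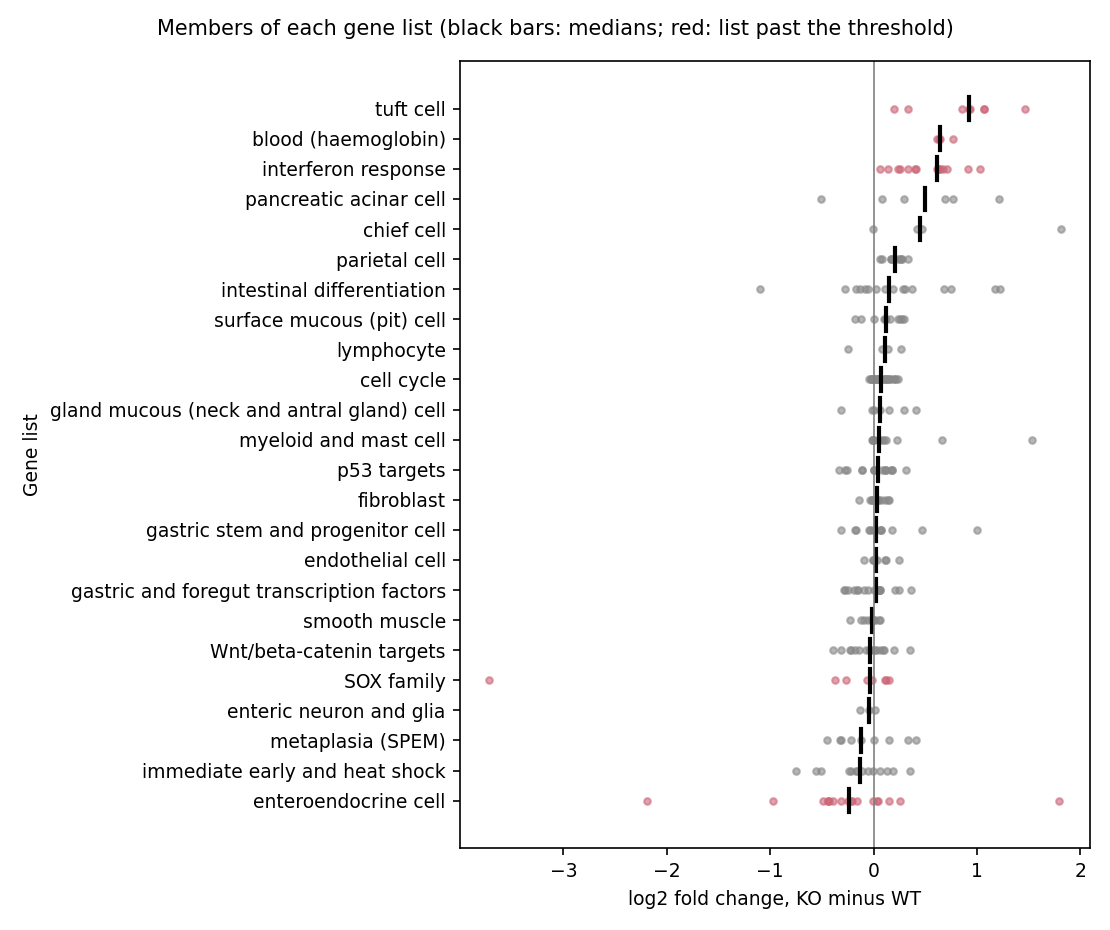
Log2 fold changes, Sox2 KO minus Sox2 WT, of the tested members of 24 gene lists (points), with the median of each list as a black bar; red lists passed the camera threshold. The tuft list has the highest median, 0.93, and the enteroendocrine list the lowest, -0.23.

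The other 19 lists tested did not pass, and 0 of their members passed over all genes. Among the cell types of the gastric glands, the median log2 fold change was 0.12 for surface mucous cells (11 tested, camera adjusted p = 0.7998), 0.06 for gland mucous cells (7 tested, 0.927), 0.45 for chief cells (4 tested, 0.194), 0.20 for parietal cells (10 tested, 0.630) and 0.02 for stem and progenitor cells (12 tested, 0.821). The secreted peptides Tff1 and Gkn2 of surface cells had log2 fold changes of 0.16 (SE 0.594) and 0.29 (SE 0.591), and Pgc and Tff2 of gland mucous cells 0.29 (SE 0.655) and 0.15 (SE 0.389). Libraries differed within a group: Atp4a, a subunit of the parietal cell proton pump, was at 307, 961 and 135 RPKM in Sox2 WT replicates 1 to 3 and its log2 fold change was 0.27 (SE 0.670), beside 0.26 (SE 0.696) for Atp4b. The chief cell genes Chia (1.81, SE 0.915) and Gif (0.42, SE 0.466) and the stem cell marker genes Prom1 (-0.04, SE 0.126) and Aqp5 (-0.31, SE 0.265) did not pass. Gastric and foregut transcription factors had a median of 0.02 (18 tested, 0.630), with Klf4 at -0.16 (SE 0.209) and Elf3 at 0.36 (SE 0.156). The metaplasia list had a median of -0.12 (9 tested, 0.273), with Gkn3 at 0.41 (SE 0.271). Leaving out 1 library gave calls. Without Sox2 WT replicate 2 the camera adjusted p was 0.00109 for chief cells and 8.7e-07 for parietal cells, both upwards, and 0.0498 for the metaplasia list, downwards. Without Sox2 WT replicate 3 it was 0.0245 for surface mucous cells, upwards, and without Sox2 KO replicate 3 it was 0.0247 for the metaplasia list, downwards. Over all alternatives the adjusted p ran from 0.00109 to 0.895 for chief cells, 8.7e-07 to 0.987 for parietal cells, 0.0245 to 0.956 for surface mucous cells and 0.0247 to 0.944 for the metaplasia list.

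Markers of intestinal differentiation had a median log2 fold change of 0.15 (16 of 30 tested, the others under the filter, camera adjusted p = 0.186). List names were matched to the deposited symbols first. Clca1 of this list was therefore the gene under that symbol, at most 0.377 RPKM in any library. The goblet cell gene Clca3 was not in the list, which was not tested with it. Adjusted over the list alone, 1 passed: Spink4, a goblet cell gene, at 1.22 (SE 0.246). The intestinal genes Krt20 (-0.13, SE 0.435) and Rbp2 (-0.08, SE 0.175) did not pass, and the enterocyte genes Sis and Mep1a were listed at 0 in all 6 libraries. Wnt/beta-catenin targets had a median of -0.04 (17 tested, 0.250), with Ccnd1 at -0.31 (SE 0.143), and passed downwards in the male libraries alone (adjusted p = 0.0386, range over all alternatives 0.0386 to 0.895). Cell cycle genes had a median of 0.07 (26 tested, 0.389), with Ccnb2 at 0.20 (SE 0.204) and Mcm6 at -0.02 (SE 0.286). The median was 0.04 for p53 targets (16 tested, 0.945; the test pointed lower), with Perp at 0.17 (SE 0.180) and Cdkn1a at 0.11 (SE 0.327), and -0.13 for immediate early and heat shock genes (14 tested, 0.273), with Junb at 0.36 (SE 0.166) and Fos at -0.17 (SE 0.444). Leaving out 1 library gave calls here too. The cell cycle list passed in both directions: upwards without Sox2 WT replicate 1 (camera adjusted p = 0.0249) or Sox2 KO replicate 1 or 2 (5.0e-05 and 0.0216), and downwards without Sox2 KO replicate 3 (1.4e-06), in which its median deviation was 0.54. Without Sox2 KO replicate 1 the immediate early list passed downwards (1.7e-04), and without Sox2 KO replicate 3 the intestinal list upwards (0.0205). Over all alternatives the adjusted p ran from 1.4e-06 to 0.944 for the cell cycle list, 1.7e-04 to 0.991 for the immediate early list and 0.00584 to 0.895 for the intestinal list.

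Among lists of other cell types, the median was -0.01 for smooth muscle (10 tested, camera adjusted p = 0.630), with Acta2 at 0.00 (SE 0.208) and Tagln at 0.06 (SE 0.236), 0.03 for fibroblasts (12 tested, 0.953), with Col3a1 at 0.11 (SE 0.151) and Dpt at -0.01 (SE 0.122), and 0.02 for endothelial cells (8 tested, 0.821), with Pecam1 at 0.11 (SE 0.167) and Eng at -0.01 (SE 0.138). With sex as a covariate, smooth muscle (adjusted p = 2.1e-05, median -0.51) and fibroblasts (adjusted p = 0.0290, median -0.16) passed downwards; over all alternatives their adjusted p ran from 2.1e-05 to 0.944 and from 0.0173 to 0.996. The covariate medians of both lists set Sox2 KO against Sox2 WT replicate 1 alone. That library had the highest median deviation for smooth muscle, 0.49, and for fibroblasts, 0.16. Enteric neurons and glia had a median of -0.04 (3 tested, 0.630), with S100b at 0.01 (SE 0.225) and Uchl1 at -0.04 (SE 0.157), and passed downwards without a filter on low values (adjusted p = 0.0415, range over all alternatives 0.0415 to 0.991). Lymphocytes had 0.11 (4 tested, 0.898), with Igj at 0.08 (SE 0.285) and Ptprc at 0.27 (SE 0.191). Myeloid and mast cells had 0.05 (13 tested, 0.194), with Lyz2 at 0.00 (SE 0.331) and C1qb at -0.01 (SE 0.202). Pancreatic acinar genes had 0.49 (6 tested, 0.601), with Clps at 1.22 (SE 0.862) and Cela1 at -0.51 (SE 0.192). Of the members under the filter, Cpa1 was listed at 0 in all 6 libraries, Prss2 had at most 1 read in any library and Amy2b at most 53. The tested members alone therefore do not show pancreatic tissue. Of 13 stratified squamous markers, Krt13 (0.11, SE 0.339) was the 1 tested, so that list was outside the family. Without Sox2 WT replicate 3 the camera adjusted p was 0.00793 for smooth muscle, downwards, and 0.0250 for myeloid and mast cells, upwards. For the latter it was, also upwards, 0.00959 without Sox2 WT replicate 1 and 0.0103 without Sox2 KO replicate 3, and for pancreatic genes, upwards, 0.00353 without Sox2 WT replicate 2. Over all alternatives the adjusted p ran from 0.00959 to 0.944 for myeloid and mast cells and from 0.00353 to 0.944 for pancreatic genes.

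Because Sox2 KO mice carried CreER at Rosa26 and Sox2 WT mice did not, genes near that locus (chromosome 6, 113067428 to 113077333, mm10) were compared with the rest. Within 10 Mb, 0 of 104 tested genes passed the threshold, against 4 of 13941 elsewhere (Fisher's exact test, two-sided, p = 1.00). With 4 calls among all genes, 0 in so small a window was nearly fixed, so that count decides nothing about genes near the locus. At an unadjusted limma p under 0.05 the counts were 2 of 104 and 440 of 13941 (Fisher's exact test, two-sided, p = 0.775). The noncoding gene at the locus itself, Gt(ROSA)26Sor, was at 3.87, 9.25 and 4.81 RPKM in Sox2 WT replicates 1 to 3 and at 0.961, 5.80 and 1.04 RPKM in Sox2 KO replicates 1 to 3 (log2 fold change -1.33, SE 0.580, limma adjusted p = 1.00).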

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

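Sex as a covariate, male libraries alone, X and Y left out, protein-coding genes alone and voom were chosen after the data were seen. The main 4 genes past the threshold became 1 with the replicate block, 181 with sample quality weights, 1 with the sex covariate, 0 in male libraries alone (583 at an unadjusted p under 0.05), 8 among protein-coding genes alone, 7 with voom and 8 at an adjusted p under 0.1, and ran from 1 to 8 without 1 library (1 without Sox2 WT replicate 3 or Sox2 KO replicate 2, 8 without Sox2 KO replicate 1, 7 without Sox2 WT replicate 1, of which 5 were sex-linked). The weights put 77.1 on Sox2 KO replicate 2 and under 1 on each other library, so that count rests on 1 library; for the others, beyond fewer genes or libraries tested, the cause was not tested. Without a filter 3 genes were called, 1 of them among the 4. The log2 fold change of Sox2 was negative throughout, from -5.00 to -3.10, and past the threshold except in male libraries alone (-3.82), where 1 Sox2 WT library was left. The 5 lists past the threshold became 0 with an estimated correlation, 1 with fry, 8 with sample quality weights and 9 in male libraries alone, and ran from 6 to 9 without 1 library. With the replicate block there were 7. Same-numbered libraries did not deviate together (correlations of 0.00879, 0.0970 and -0.0740), so no strong pairing by number was seen, though a weaker pairing is not excluded. Calls near Rosa26 were 0 except for 2 with sample quality weights. Tuft and enteroendocrine lists were called in 22 of 24 alternatives each. Among 114 single genes, 30 results lost and 54 gained a call, and 94 changed sign, none of them called in the main comparison; among 24 lists, 16 lost and 32 gained a call, and 51 changed sign, none of them called in the main comparison. At 0.5 RPKM and below, the pseudocount limits any fold change.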

Other observations

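All tests in this part were chosen after the results they bear on were seen. The genes named in the next 2 paragraphs lie outside the naming rule unless the report gave them, and were also chosen after their values were seen; none of the genes so chosen passed the threshold over all genes.

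Some genes, picked because their groups do not overlap, had higher values in each Sox2 KO library. The chitinase-like gene Chi3l4 was at 3.14, 0.726 and 40.8 RPKM in Sox2 WT replicates 1 to 3 and at 213, 1357 and 466 RPKM in Sox2 KO replicates 1 to 3 (log2 fold change 6.50, limma adjusted p = 0.356). Clca3, a goblet cell secretory gene, was at 553 ± 441 and 2599 ± 782 RPKM (SD, n = 3 each; log2 fold change 2.62, adjusted p = 0.838). The mast cell proteases Mcpt1 and Mcpt2 had log2 fold changes of 1.53 and 0.66, Arg1 of 1.03 and the chemokine gene Ccl8 of 1.07. The goblet cell gene Tff3 (0.74) and the mast cell genes Cpa3 (0.23) and Cma1 (-0.01) overlapped between the groups, as did the goblet cell gene Muc2, which was under the filter.

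Neither of 2 paralogs of Gsdmc2 passed. Gsdmc4 was at 1.88 ± 0.337 RPKM in Sox2 WT and 0.444 ± 0.176 RPKM in Sox2 KO, and Gsdmc3 at 1.05 ± 0.114 and 0.139 ± 0.120 RPKM (SD, n = 3 each; limma adjusted p = 0.151 and 0.152). Reads shared among these paralogs were not resolved. Sox2ot, a noncoding RNA named for its overlap with Sox2, was under the filter and not tested: it was at 0.0810, 0.0616 and 0.0632 RPKM in Sox2 WT replicates 1 to 3 and at 0.224, 0.226 and 0.265 RPKM in Sox2 KO replicates 1 to 3. Isx, of the intestinal list and also under the filter, had 3, 0 and 3 reads in Sox2 WT and 23, 28 and 16 reads in Sox2 KO replicates 1 to 3. Cdx2, likewise untested, had 13, 1 and 16 and then 9, 52 and 50 reads. The groups overlapped for Cdx2, as they did for Cdx1 and Guca2b of that list.

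The higher tuft markers could come from more tuft cells, from other cells or from the make-up of the groups. Leukocytes, which also express Alox5 and Ptgs1, would have raised their own markers. The median log2 fold change of 17 lymphocyte and myeloid genes was 0.0795 (upper quartile 0.138), under the lower quartile of the tuft members, 0.72. The abundant Lyz2 was at 61.0 RPKM in Sox2 WT and 60.3 RPKM in Sox2 KO. Of the 17, the mast cell genes Mcpt1 and Mcpt2 were higher in each Sox2 KO library (log2 fold changes 1.53 and 0.66). Cpa3 and Cma1 overlapped between the groups, and the median does not speak to single kinds of leukocyte. A lower share of the main epithelial types would have raised all others alike, while 65 genes of 6 other cell types had a median of -0.0015. A second list of tuft-enriched genes, written before its values were seen apart from Ascl2, had 12 tested members and a median of 0.40 (camera p = 7.9e-09, p = 0.0164 with an estimated correlation), which is consistent with more tuft cells, though some of its genes are also expressed by leukocytes. A type 2 immune response, in which tuft and goblet cells expand, stays open: a second list of its genes had 10 tested members and a median of 0.0862 (camera p = 0.00587, p = 0.103 with an estimated correlation), with Siglec5 at 1.31 and the mast cell gene Mcpt4 at -0.18. Sex cannot be told apart from genotype with 1 male Sox2 WT library, against which the tuft median was 1.06, and CreER itself, which was not tested, also stays open.

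The higher values of Itln1 and Zg16 might reflect duodenal tissue in the Sox2 KO samples, which would bring abundant enterocyte transcripts. The brush-border enzyme genes Sis, Mep1a, Mep1b and Lct were at most 0.0152 RPKM in any Sox2 KO library. They were taken from genes under the filter, so a low level was nearly fixed in advance and decides little. Of other intestinal genes under the filter, Isx had more reads in each Sox2 KO library, while Cdx2, Cdx1 and Guca2b overlapped between the groups. Apart from these, 7 enterocyte genes with a Sox2 WT mean under that of Zg16 had an upper quartile of 0.34. The log2 fold changes of Itln1 and Zg16 were 4.93 and 4.06, which argues against duodenal tissue as their whole source. The hormone genes Gip (1.12) and Cck (1.79) and the enterocyte gene Fabp1 (1.18) had higher means in Sox2 KO, so a small share of such tissue is not excluded for other genes. A strain variant at Itln1 stays open on a mixed background: 3 of 43 tested genes within 1 Mb had an unadjusted limma p under 0.05. That does not decide it, since a variant in 1 gene need not move its neighbours. A type 2 immune response, in which goblet cells expand, also stays open for both genes. Sox2 deletion, CreER and sex are open too, and with sex as a covariate the log2 fold change of Zg16 was 2.84 (limma adjusted p = 0.479, range over all alternatives 0.00572 to 0.707).

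Fewer endocrine cells of every kind, as the whole cause of the lower Tph1, would lower the abundant endocrine genes as much. Gast, Sst, Ghrl, Chgb and Chga, the 5 most abundant members of the list, had a median log2 fold change of -0.00808, and each of the 5, less 2 SE, lay above the value of Tph1 plus 2 SE. Chgb was nevertheless lower, at 128 ± 26.9 RPKM in Sox2 WT and 64.3 ± 6.44 RPKM in Sox2 KO (SD, n = 3 each; log2 fold change -0.97, limma adjusted p = 0.298), so a smaller loss of endocrine cells stays open. A change in Tph1-expressing cells may also be a candidate explanation and was not tested.

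The 6 libraries can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 4 genes past the threshold, 1 of 10 splits with as many, and the highest other split gave 1. For gene lists the real split gave 5, 8 of 10 splits gave as many or more, and the highest other gave 10. The absolute median of the tuft list was 0.93 in the real split and 0.56 in the highest other; that of the enteroendocrine list was 0.23 and 0.29.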
